A study of Mus musculus with 40 samples.

How the data were processed

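RRBS libraries were made from pro-B and follicular B cells of WT, Tet2KO, Tet3KO and DKO C57/bl mice, 3 per group and 24 in all. A further 16 samples of the series, from RNA sequencing, were not analysed here. Groups, sexes and ages were taken from the sample labels, and libraries are named by the running number in their titles.

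The deposited table gives, per the file headers, the chromosome, start and end of 971845 tiles of 100 bp and a column of values per library. The values deposited by the authors are a methylation fraction between 0 and 1 for each tile and library, with no read counts or coverage. Trim Galore and methylKit are named in the submitters' processing notes, without versions, together with the builds mm9 and hg19; TopHat2 and Cuffdiff 2.1.1 are also named and belong to RNA sequencing. The aligner, the bisulfite conversion rate and the coverage minimum were not given in the sources used here. The mouse coordinates were taken as mm9, since tiles of chromosome 1 reach 197193600, and they were not converted. No value was given for 175118 tiles in any library. Because depth was unknown, no counting interval could be given, and a level of 0 or 100% can rest on few reads. Libraries had values for 24600 to 631415 tiles, which is used as a rough measure of depth.

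Fractions were multiplied by 100 to percentages. The design, the test, the rule for naming regions and most alternatives were fixed before the data were examined. The design had a count model for tables with reads and limma for tables with levels only, and the latter was used. Limma 3.58.1 (in R 4.3.3, with version 1.17.8 of the data.table package) was fitted to the level of each tile with the 8 groups as a factor, over all 24 libraries (16 residual degrees of freedom), with a trended prior spread. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 (two-sided) and a difference of group means of at least 20 percentage points. Chromosomes X and Y were left out, since Tet2KO mice were all female and the other groups mixed. The planned set held 16026 tiles with a value in all 24 libraries, and the wide set held 200813 tiles with values in at least 2 of 3 libraries of every group. Leading with the wide set was decided after the numbers of tiles had been seen. Tiles of intermediate level were the 12905 with a mean of 20 to 80% among the 128596 autosomal tiles with a value in the 23 libraries other than pro-B Tet3KO library 8. The classes of called tiles by level use the wide set.

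Called tiles of 1 direction within 500 bp were joined. Regions of at least 2 called tiles in which the 3 libraries of one group lay above those of the other were ranked by mean difference, and at most 10 per direction were named for the main comparisons (37 in all); the separation was not asked of the interaction. A region's level is the mean over its tiles, and where a library had no value at a region n is lower. The annotation at hand was of another mouse build, so regions carry no gene names, the planned tests of 12 gene lists were not run, and Tet2 and Tet3 themselves could not be examined as a check of the genotypes.

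Group means per library were compared by two-sided exact permutation tests; 3 against 3 libraries cannot give a p under 0.1. Tiles that fell in WT were chosen with 1 WT library of each stage left out and measured with those libraries. The same idea was applied, after the data were seen, to tiles higher in follicular DKO and to tiles called in pro-B knockouts. For pro-B Tet3KO the held-out choices used libraries 7 and 9 only, 6 choices in place of 9. Library 8 had a value at 20198 of the 200813 wide tiles, so most tiles were then chosen on 1 Tet3KO library. Also added after the data were seen were a fit within each stage, a paired fit of matched pro-B and follicular libraries, a fit without the library of fewest tiles, every alternative combined with the wide set, and 6 further contrasts between genotypes, of which only that of DKO with the sum of the single knockouts is reported.

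The alternatives were logit values, fits of only the compared groups, sex as a covariate, centring of each library, X and Y kept, 30 points in place of 20, sex and age strata as a block, the wide tile set, and each library left out in turn. Leaving out a library leaves 1 value of a group at part of the wide set, where that value is assumed to vary like the other groups. The procedure was tested on simulated data in which each library's deviations were drawn from tiles of similar level. The spread of a single tile was therefore not kept. In the planned set it recovered 3 of 100 tiles raised by 25 points and 28 of 100 raised by 40 points for follicular DKO against WT, with 0 false calls. In the wide set it recovered 0 and 1 of 100. Tiles that were not called can therefore still differ. The same fit called 257 wide tiles higher in the real data, so the simulated setting is unlike the data. Its calls in unchanged groups, given below, are a rough guide and do not measure chance.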

Results

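Reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation in CpG-rich restriction fragments, was applied to 24 libraries of B-lineage cells from C57/bl mice. The libraries formed 8 groups of 3. Pro-B cells, an early stage of B-cell development, and follicular B cells, a mature resting population, were each taken from wild-type (WT) mice, from mice lacking Tet2, from mice lacking Tet3, and from double-knockout (DKO) mice lacking both. Tet2 and Tet3 are dioxygenases that oxidise 5-methylcytosine, a step towards its removal, and per the labels they were deleted under the Mb1 promoter, which is active from the earliest B-lineage stages. The comparisons ask where methylation changed between the pro-B and follicular stages, and how those levels differed when the enzymes were missing. The table of methylation levels gave a fraction for each 100 bp tile and no read counts, so the depth behind each value was unknown. The number of tiles with a value, the nearest measure of depth at hand, ran from 24600 in pro-B Tet3KO library 8 to 631415 in pro-B Tet2KO library 5, with a median of 525374. The labels give a sex and an age for each library but do not say that libraries of a group came from separate mice, so the p-values measure only the spread between these libraries.

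**Figure D1:**
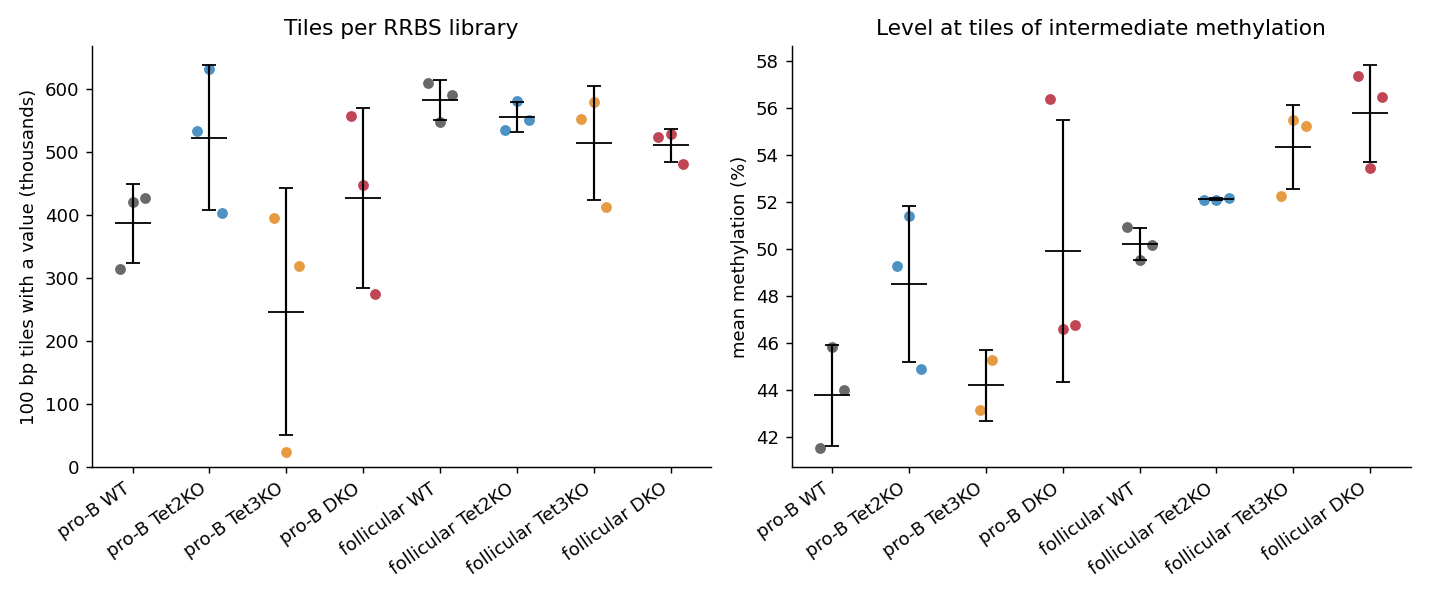
The left panel plots the number of 100 bp tiles with a value for each library by group, and the right panel plots the mean methylation (%) at 12905 tiles of intermediate level; points are libraries, lines are group means and bars are SDs. Pro-B Tet3KO library 8, with 24600 tiles, is absent from the right panel, and the follicular groups rise from 50.2% in WT to 55.8% in DKO.

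Follicular cells were more methylated when Tet2 or Tet3 was missing, with the highest group mean in the DKO. At tiles of intermediate methylation (a mean of 20 to 80%), the follicular level was 50.2% ± 0.691 in WT, 52.1% ± 0.0418 in Tet2KO, 54.3% ± 1.79 in Tet3KO and 55.8% ± 2.06 in DKO (SD, n = 3 each). In each knockout all 3 libraries lay above the 3 WT libraries (two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 can give). DKO and Tet3KO overlapped, with DKO library 23 at 53.5% and Tet3KO libraries 20 and 21 at 55.5% and 55.2%. The mean number of tiles ran the other way, from 581199 in WT through 554699 in Tet2KO and 513931 in Tet3KO to 510280 in DKO. Within follicular genotypes the level had little relation to the number of tiles (r = -0.162). Depth and genotype were nevertheless not separated in the follicular group means. Over the 16026 autosomal tiles with a value in all 24 libraries, most of which carry little methylation, the same order of group means was seen at 10.9% ± 0.092, 11.1% ± 0.022, 11.4% ± 0.222 and 11.6% ± 0.22. In pro-B cells the means over these tiles were 10.1% ± 0.143 in WT, 10.6% ± 0.26 in Tet2KO, 10.4% ± 0.211 in Tet3KO and 10.8% ± 0.424 in DKO (n = 3 each). The exact permutation p against pro-B WT was 0.1 for DKO and Tet2KO and 0.2 for Tet3KO. At intermediate tiles pro-B libraries lay above WT by 6.14 points in DKO (exact permutation p = 0.1), 4.74 in Tet2KO with overlap (exact permutation p = 0.2) and 0.430 in Tet3KO (2 libraries, exact permutation p = 1). The DKO difference leaned on library 10 at 56.4%, with libraries 11 and 12 at 46.6% and 46.8%. Pro-B Tet2KO libraries had a mean of 521956 tiles against 386678 in WT, and depth was not separated from genotype here. WT follicular libraries lay 0.757 points above WT pro-B libraries (exact permutation p = 0.1), and the same gap was 0.817 points in DKO, 0.511 in Tet2KO and 1.01 in Tet3KO (exact permutation p = 0.1 for each). At intermediate tiles the gap was 6.44 points in WT, 3.59 in Tet2KO and 10.1 in Tet3KO (exact permutation p = 0.1 for each). In DKO it was 5.85 points there and 1.16 over the 128596 tiles with a value in 23 libraries, with overlap between the stages (exact permutation p = 0.2 for both). At intermediate tiles pro-B DKO library 10 lay within the follicular DKO range of 53.5% to 57.4%. Without that library the DKO gap there would be larger. At the follicular intermediate tiles the DKO rise of 5.55 points was close to the 6.00 points that the Tet2KO and Tet3KO rises add up to, with a difference of -0.454 points (SE 1.62).

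Tile-by-tile tests were run on those 16026 tiles, as planned, and on a wide set of 200813 tiles with values in at least 2 libraries of every group. Pro-B Tet3KO library 8 limited the planned set, so the wide set, which had been planned for comparison, leads the account of single regions. That choice was made after the tile numbers were seen. A tile was called when limma's adjusted p was under 0.05 and the group means differed by at least 20 percentage points. Neighbouring called tiles were joined to regions, which are named by mm9 coordinates because no gene annotation of that build was used here. The named regions were picked on the libraries they are measured in, so their differences are overstated. For this reason, mean levels are also given for libraries held out of the choice of tiles.

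Between the pro-B and follicular stages of WT mice, methylation fell at 95 tiles and rose at 268 of the wide set. In WT libraries held out of the choice, the change was -13.9 points ± 3.16 at 136 to 176 tiles chosen as falling. It was only 5.41 points ± 2.12 at 335 to 837 tiles chosen as rising (SD, n = 3 each). Both lay below the difference asked of a called tile. The chosen lists were longer than the called tiles, so these values do not show how much of the called tiles is noise. Among regions of 2 or more called tiles, the largest fall was at chromosome 4, 140491701 to 140491900. It went from 97.6% ± 2.86 in pro-B to 29.9% ± 3.09 in follicular cells (SD, n = 3 each). Chromosome 3, 88419801 to 88420000, fell from 90.8% ± 8.94 to 28.5% ± 7.53, and chromosome 4, 45800601 to 45800800, from 97.0% ± 5.22 to 58.6% ± 7.47. Among regions of 2 or more called tiles without overlap between the stages, the largest rise was at chromosome 13, 24939101 to 24939300. It was listed at 0 in the 3 pro-B libraries and stood at 76.8% ± 2.62 in follicular cells. Chromosome 18, 64609501 to 64609700, likewise went from 0 to 62.2% ± 6.47, and chromosome 6, 127464301 to 127464500, from 48.8% ± 7.97 to 86.0% ± 1.61. Pro-B knockout libraries with more tiles were not all at 0 at the chromosome 13 region. Tet2KO library 5 stood there at 36.9% and DKO library 10 at 38.5%. At the chromosome 18 region library 10 stood at 38.4% and library 5 at 0. Whether the zeros come from the stage or from few reads was not tested. The falling tiles formed 89 regions, 6 of them with 2 or more called tiles, and the rising tiles formed 254 regions, 14 of them with 2 or more. Among the falling regions, chromosome 2, 31353201 to 31353400, went from 94.7% ± 1.37 (n = 2) to 63.9% ± 2.06 (n = 3), and chromosome 15, 58889101 to 58889300, from 97.3% ± 0.469 to 68.2% ± 4.92 (n = 3 each).

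Over the planned set 1 tile fell and 8 rose in WT, with 1052 of the 16026 tiles at an unadjusted p under 0.05. The falling tile, chromosome 11, 45538601 to 45538700, named after its values were seen, went from 75.7% ± 6.63 to 45.0% ± 5.29 (n = 3 each, adjusted p = 0.0197). Unchanged groups simulated with the spread of these libraries gave 0 falling and 22 rising tiles in the wide set. With each library centred on a common level, the wide set split into 96 falling and 155 rising tiles (61.8% rising) in place of 73.8% rising. Without pro-B WT library 1, 2 or 3 the wide set gave 168, 187 or 209 falling and 498, 1138 or 1000 rising tiles, with a single pro-B value left at part of the tiles. Without follicular WT library 15 it gave 173 rising tiles. With sex and age strata as a block, which pairs the WT libraries of the 2 stages, it gave 57 falling and 95 rising tiles. With each pro-B library matched to a follicular library of its genotype, sex and age as a block, which leaves 8 residual degrees of freedom, it gave 11 falling and 16 rising tiles. The planned falling count was 2 without pro-B WT library 1 or 2. The named tile itself was no longer called without pro-B WT library 1 or 3, or with only the compared groups fitted. The planned rising count was 2 without pro-B WT library 1 or follicular WT library 13 and 5 without pro-B WT library 3 or follicular WT library 15.

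In follicular cells lacking both enzymes, methylation was higher than in WT at 257 tiles of the wide set and lower at 2. Regions that were almost unmethylated in WT follicular cells were largely methylated in the DKO. Chromosome 11, 44306901 to 44307200, stood at 3.91% ± 2.7 in WT and 85.0% ± 4.77 in DKO (SD, n = 3 each), and chromosome 14, 34003101 to 34003400, at 1.01% ± 1.11 and 75.6% ± 0.453. Chromosome 5, 123774301 to 123774600, was at 6.64% ± 1.81 and 85.1% ± 4.6. Chromosome 19, 37546001 to 37546200, was at 3.26% ± 3.9 and 75.9% ± 9.02, and chromosome 7, 118067001 to 118067400, at 9.54% ± 3.69 and 81.9% ± 4.75. The 257 tiles formed 228 regions, 25 of them with 2 or more called tiles. Of the other named regions, chromosome 7, 106036501 to 106036700, went from 4.53% in WT to 77.1% in DKO, and chromosome 7, 16549301 to 16549600, from 7.15% to 72.2%. Chromosome 5, 36677101 to 36677300, went from 18.3% to 85.9%. Chromosome 5, 149692001 to 149692200, went from 23.2% to 94.6%, and chromosome 3, 88419801 to 88420000, from 28.5% to 92.4%. Of the called tiles 85 had a mean level under 20%, 144 lay between 20 and 80% and 28 above 80%. The lower tiles were named after their values were seen. Chromosome 3, 95192101 to 95192200, was at 96.9% ± 0.12 in WT and 74.8% ± 1.96 in DKO, and chromosome 8, 117966901 to 117967000, at 99.3% ± 1.2 and 78.8% ± 4.59 (n = 3 each). Both lost their call on logit values and without WT library 13, 14 or 15 or DKO library 22 or 24, and the tile of chromosome 3 also without DKO library 23.

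The adjusted p-values of the tiles in these 10 regions ran from 2.38e-06 to 0.0206, and 11690 of the 200813 tiles had an unadjusted p under 0.05. Among the planned tiles limma called 6 higher and 0 lower in the follicular DKO, with 1151 of 16026 tiles at an unadjusted p under 0.05. These 6 tiles were named after their values were seen. On chromosome 4 they lay at 133371101 to 133371200 (22.3 points higher) and 135259801 to 135259900 (27.6 points). On chromosome 7 they lay at 135325301 to 135325400 (24.4 points) and 139883901 to 139884000 (48.7 points). The others were chromosome 6, 143343101 to 143343200 (56.0 points), and chromosome 12, 110309601 to 110309700 (40.8 points). The count of 257 was 154 without follicular WT library 14, 161 without WT library 15 and 425 without DKO library 23. It was 138 on logit values, 449 with the spread estimated within the follicular stage, and 17 when only the WT and DKO follicular libraries were fitted, which leaves 4 residual degrees of freedom. The 2 lower tiles became 15, 17 or 15 without DKO library 22, 23 or 24, and 7 or 6 without WT library 13 or 15. The 6 planned tiles became 25 without DKO library 23. On logit values 4 of the named 6 lost their call, all but 135259801 to 135259900 on chromosome 4 and the tile of chromosome 12, and with only the 2 groups fitted all 6 lost it. The tile at 135325301 to 135325400 also lost it within the follicular stage and without WT library 13, 14 or 15 or DKO library 22. The tile at 133371101 to 133371200 lost it within the stage and without DKO library 24.

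**Figure D2:**
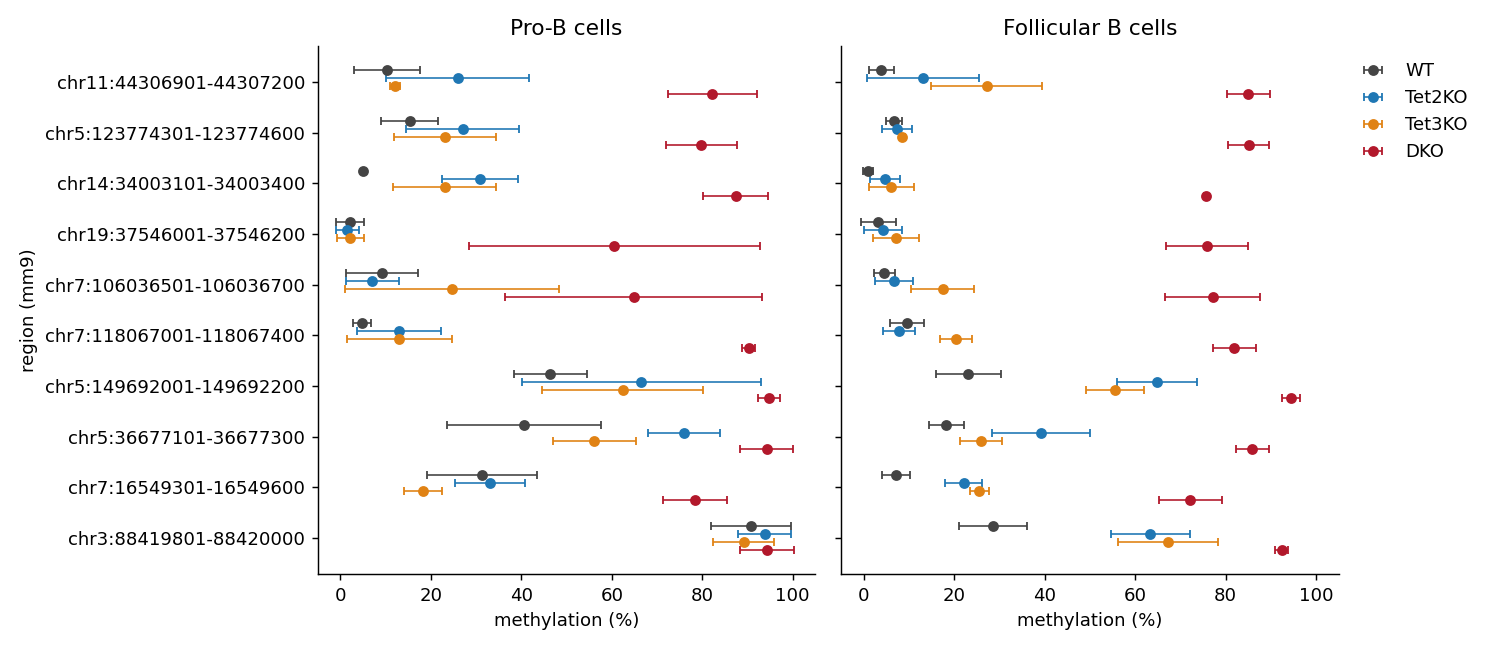
Mean methylation (%) of the 4 genotypes at the 10 named regions that were higher in follicular DKO than in follicular WT, in pro-B cells (left) and follicular B cells (right); points are group means over libraries and bars are SDs (n = 2 or 3). The follicular DKO means lie between 72.2% and 94.6%, and the follicular WT means between 1.01% and 28.5%.

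The single knockouts stood between WT and DKO at part of these regions and near WT at others. At chromosome 3, 88419801 to 88420000, follicular cells were at 28.5% ± 7.53 in WT, 63.3% ± 8.72 in Tet2KO, 67.3% ± 11.1 in Tet3KO and 92.4% ± 1.44 in DKO (n = 3 each). Chromosome 5, 149692001 to 149692200, was at 64.9% ± 8.86 in Tet2KO and 55.6% ± 6.34 in Tet3KO. Chromosome 5, 123774301 to 123774600, was at 7.31% ± 3.28 in Tet2KO and 8.54% ± 0.564 in Tet3KO against 6.64% ± 1.81 in WT. Chromosome 14, 34003101 to 34003400, was at 4.69% ± 3.4 in Tet2KO and 6.12% ± 5.01 in Tet3KO. Follicular Tet2KO had 6 tiles higher and 0 lower than WT in the wide set, and Tet3KO 20 higher and 0 lower. All 6 Tet2KO tiles and 19 of the 20 Tet3KO tiles were among the 257 of the DKO. Independent lists would share 0.00768 and 0.0256 tiles. These lists share the WT libraries, so part of the excess can come from them. Unchanged groups simulated against those libraries gave 0 calls in each comparison. That simulation recovered only 0 of 100 wide tiles raised by 25 points and 1 of 100 raised by 40 in DKO. It therefore cannot measure the part from shared libraries.

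Limma called 0 planned tiles in follicular Tet2KO and 0 in Tet3KO, with 622 and 797 tiles at an unadjusted p under 0.05. Of the wide set 5767 and 7956 tiles were under it. These were 3.88% and 4.97% of the planned tiles and 2.87% and 3.96% of the wide tiles. A share of 0.05 would be reached without any difference, so these counts hold no excess. The Tet3KO count of the planned set was 2, 1 or 1 without Tet3KO library 19, 20 or 21. The 6 Tet2KO tiles of the wide set became 19, 12 or 11 without WT library 13, 14 or 15, and 13, 20 or 10 without Tet2KO library 16, 17 or 18. The 20 Tet3KO tiles became 33 without WT library 13 and 64 or 54 without Tet3KO library 19 or 20.

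Tiles were next chosen as higher in follicular DKO with 1 WT and 1 DKO library left out, and measured in the libraries left out. This was done over 9 such choices of 177 to 316 tiles, and was added after the data were seen. In held-out follicular libraries the level was 17.3% ± 1.52 in WT and 51.4% ± 8.57 in DKO (n = 3 each), a difference of 34.0 points (SE 5.03). At the same tiles follicular Tet2KO stood at 24.2% ± 0.303 and Tet3KO at 31.4% ± 1.06. The follicular genotypes did not overlap in any pair, in the order WT, Tet2KO, Tet3KO, DKO (exact permutation p = 0.1 for each pair). In pro-B cells, whose libraries took no part in the contrast, WT stood at 26.5% ± 2.12, Tet2KO at 32.3% ± 1.51 and DKO at 47.7% ± 3.27 (n = 3 each; exact permutation p = 0.1 for each knockout against WT). Pro-B Tet3KO libraries 7 and 9 stood at 33.6% and 34.7%, and library 8, with few tiles, at 2.61%. WT follicular cells lay below WT pro-B cells at these tiles, with a difference of -9.15 points (SE 1.51, exact permutation p = 0.1). DKO follicular and pro-B cells differed by 3.69 points (SE 5.30, exact permutation p = 0.5). The tiles were chosen for a low WT and a high DKO level in follicular cells. That choice favours a fall between stages in WT and none in DKO, so these 2 values do not test demethylation. The DKO-to-WT difference stayed above 0 but was 17.7, 20.1 or 18.6 points when DKO library 22, 23 or 24 was dropped from the whole procedure, which leaves a single DKO library for choosing the tiles.

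**Figure D3:**
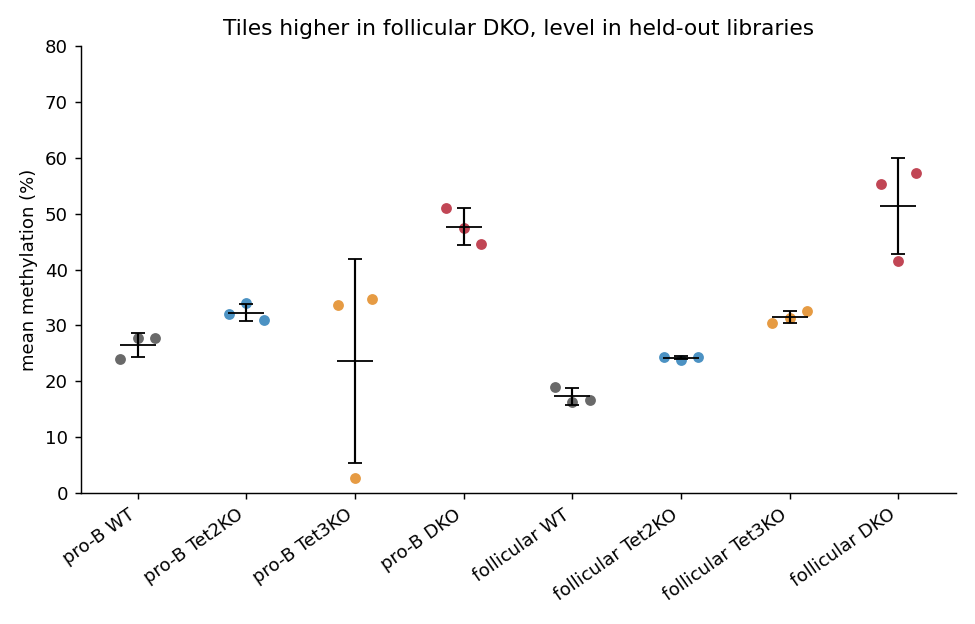
Mean methylation (%) per library at tiles called higher in follicular DKO than WT, with follicular WT and DKO libraries measured only where they were held out of the choice; points are libraries, lines are group means and bars are SDs (n = 3). Follicular libraries rise from 17.3% in WT through 24.2% in Tet2KO and 31.4% in Tet3KO to 51.4% in DKO, and the low pro-B Tet3KO point at 2.61% is library 8.

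The demethylation seen between the WT stages was also followed in the knockouts. At chromosome 4, 140491701 to 140491900, where WT follicular cells fell to 29.9%, follicular Tet2KO cells stood at 52.7% ± 1.8, Tet3KO at 73.0% ± 8.83 and DKO at 82.0% ± 9.99 (n = 3 each). At chromosome 4, 45800601 to 45800800, where WT follicular cells fell to 58.6%, the 3 follicular knockout groups stood at 90.0% ± 2.18, 89.5% ± 2.93 and 92.8% ± 2.93. Of the 95 tiles that fell in WT, 42 were among the 257 that were higher in follicular DKO, where independent lists would share 0.122. Both lists use the WT follicular libraries, so part of the excess can come from them. Simulated unchanged groups gave 0 falling tiles in WT and 0 calls in DKO. The simulation recovered at most 1 of 100 raised wide tiles in DKO, so it cannot measure that part. Tiles of the wide set were therefore chosen as falling in WT with 1 WT library of each stage, of the same sex and age, left out. The change was measured with the libraries left out, over 3 choices of 136 to 176 tiles. The change was -13.9 points ± 3.16 in WT, -11.6 ± 0.0821 in Tet2KO, -8.53 ± 0.474 in Tet3KO and -2.76 ± 0.164 in DKO (SD, n = 3 follicular libraries each). Each knockout value is set against the mean of its pro-B group, so these SDs hold no spread of the pro-B knockout libraries.

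The DKO change was smaller than the WT change by 11.1 points, with no overlap (two-sided exact permutation p = 0.1, the smallest possible), the Tet3KO change by 5.32 points (exact permutation p = 0.1) and the Tet2KO change by 2.26 points (exact permutation p = 0.2). The values of a knockout share 1 pro-B mean, so they are not independent and these p-values leave out the pro-B knockout spread. The DKO value of 11.1 points was 4.06, 2.85 or 2.42 without pro-B WT library 1, 2 or 3 and 5.92 without follicular WT library 13. The same procedure on the planned set chose only 1 or 2 tiles, and the DKO value of -2.41 points (exact permutation p = 0.9) had the opposite sign. It was 0.664 with tiles chosen on all WT libraries, 3.72 without pro-B WT library 1 and 1.83 without follicular WT library 13. It was -5.43 or -4.57 without pro-B WT library 2 or 3, and -3.78 or -1.17 without pro-B DKO library 10 or 12. It was -9.03 or -5.11 without follicular WT library 14 or 15, and -4.67 or -1.04 without follicular DKO library 22 or 23.

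**Figure D4:**
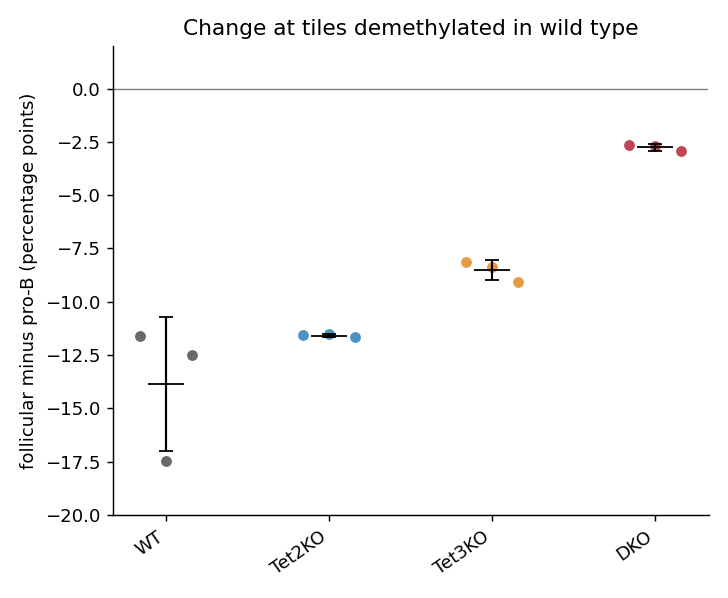
Change in mean methylation from pro-B to follicular cells (percentage points) at tiles that fell in WT, measured in libraries held out of the choice; points are follicular libraries, lines are means and bars are SDs (n = 3). The change is -13.9 points in WT, -11.6 in Tet2KO, -8.53 in Tet3KO and -2.76 in DKO.

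Between stages within each knockout, the planned set gave 1 falling tile in DKO, 1 in Tet2KO and 3 in Tet3KO. Chromosome 11, 45538601 to 45538700, the falling tile of WT, was the falling tile of DKO and Tet2KO and one of those of Tet3KO, so it was called in all 4 genotypes. With sex and age strata as a block it was no longer called in WT and Tet2KO, and with matched libraries as a block it was no longer called in WT, Tet2KO and DKO. Its call was also lost in WT without pro-B library 1 or 3, in Tet2KO with centring or without pro-B library 4, and in every genotype with only the compared groups fitted. In follicular cells it stood at 45.0% ± 5.29 in WT, 42.9% ± 1.83 in Tet2KO, 41.9% ± 2.81 in Tet3KO and 42.5% ± 0.717 in DKO, against 72.6% to 80.1% in the pro-B groups (n = 3 each). The other Tet3KO tiles, all named after their values were seen, were chromosome 5, 93780901 to 93781000 (92.6% ± 12.8 to 47.3% ± 22.5) and chromosome 18, 61994701 to 61994800 (35.6% ± 16.1 to 5.38% ± 2.93). Both lost their call on logit values, with only the compared groups fitted and without library 8, 9, 20 or 21, and the tile of chromosome 18 also without library 19. In the wide set 59 tiles fell and 279 rose in DKO, 40 fell and 73 rose in Tet2KO, and 76 fell and 762 rose in Tet3KO. Unchanged groups simulated with each library's spread at similar levels gave 1 falling and 10 rising in DKO, 0 and 0 in Tet2KO, and 7 and 124 in Tet3KO. With sex and age strata as a block 26, 17 and 14 tiles fell in DKO, Tet2KO and Tet3KO, and with matched libraries as a block 13, 6 and 99.

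With libraries centred, the wide set gave 19 falling and 18 rising tiles in Tet2KO (48.6% rising in place of 64.6%) and 767 falling and 2705 rising in Tet3KO (77.9% in place of 90.9%). The falling counts of the wide set were 148 or 163 without pro-B DKO library 10 or 11, 61 without pro-B Tet2KO library 5, and 720 or 263 without pro-B Tet3KO library 7 or 9. The planned counts were 4, 3, 3 or 3 without pro-B DKO library 10, 11 or 12 or follicular DKO library 24. They were 0 or 2 without pro-B Tet2KO library 4 or follicular Tet2KO library 16, and 15, 6, 1 or 1 without pro-B Tet3KO library 7 or 9 or follicular Tet3KO library 20 or 21.

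In pro-B cells the DKO was already more methylated than WT at regions that were also higher in the follicular DKO. Chromosome 7, 118067001 to 118067400, stood at 4.79% ± 2 in WT and 90.3% ± 1.4 in DKO pro-B cells (SD, n = 3 each). Chromosome 11, 44306901 to 44307200, stood at 10.3% ± 7.3 and 82.2% ± 9.81, and chromosome 7, 139883701 to 139884000, at 0.877% ± 1.52 and 91.7% ± 8.33. Of the 376 tiles called higher in pro-B DKO, 70 were among the 257 of the follicular DKO, where independent lists would share 0.481. The contrasts share no library but do share the estimate of the spread. Follicular libraries were outside the pro-B contrast but shared in its spread and in the filter of wide tiles. In them the 376 tiles stood at 72.2% ± 2.16 in DKO and 51.9% ± 0.243 in WT (n = 3 each), a difference of 20.3 points (exact permutation p = 0.1). The other pro-B lists differed less in follicular libraries, by 1.33 points at the 88 tiles lower in DKO, 1.60 and 1.11 at the 112 higher and 26 lower in Tet2KO, and 3.31 and 0.888 at the 330 higher and 516 lower in Tet3KO. For the lower tiles this was the opposite direction. Also named were chromosome 5, 115619001 to 115619200 and 123774301 to 123774500, chromosome 4, 94742501 to 94742700, and chromosome 14, 34003001 to 34003400. The last were chromosome 2, 4454101 to 4454300, chromosome 3, 126649201 to 126649400, and chromosome 13, 55628701 to 55628900. The DKO means of these 7 ran from 67.1% to 99.4%, and lay 65.6 to 82.5 points above WT.

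The pro-B tile counts carried much noise between libraries, although the tiles higher in DKO held a part that also differed in follicular cells. The wide set gave 376 higher and 88 lower tiles in DKO, 112 and 26 in Tet2KO, and 330 and 516 in Tet3KO. In pro-B libraries held out of the choice, the tiles chosen as higher in DKO differed from WT by 4.88 points (-2.50 to 11.8 over the choices), against 47.5 in the libraries that chose them. With the spread estimated within the pro-B stage this held-out difference was -2.38 points (-11.0 to 3.47). Tiles chosen as lower in DKO differed by 1.98 points, the other direction. For Tet3KO the held-out differences were 0.589 points at 928 to 2586 tiles chosen as higher and 0.695 at 2631 to 3951 chosen as lower, against 44.4 and -45.4. Most of those tiles were chosen on a single Tet3KO library, so the lists are larger and noisier than the called tiles. For Tet2KO the held-out differences were 0.943 and 3.53 points, against 45.0 and -38.3. The DKO and Tet2KO lists were also longer than the called tiles. They held 741 to 1848 higher and 235 to 1086 lower tiles in DKO, and 369 to 1008 and 116 to 344 in Tet2KO. Part of these tiles had a single library of a group left for the choice. The held-out values therefore do not show how much of the called tiles is noise. Unchanged groups simulated with each library's spread at similar levels gave 38 higher and 20 lower tiles for DKO, 32 and 7 for Tet2KO, and 87 and 195 for Tet3KO. The spread within pro-B groups was larger, with residual SDs of 4.23 to 8.04 points against 2.63 to 3.66 in follicular groups.

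One planned tile was changed in pro-B DKO, chromosome 7, 139883901 to 139884000, named after its values were seen. It was listed at 0 in WT and stood at 86.8% ± 17.7 in DKO (n = 3, adjusted p = 5.55e-06), and lost its call only with the 2 compared groups fitted alone. In DKO 853 tiles had an unadjusted p under 0.05, and centring gave 38 higher and 6 lower (86.4% higher in place of 100%). Limma called 0 tiles in pro-B Tet2KO and 0 in Tet3KO in that set, with 678 (4.23%) and 947 (5.91%) at an unadjusted p under 0.05. With the spread estimated within the pro-B stage, the wide set gave 35 changed tiles in DKO, 13 in Tet2KO and 88 in Tet3KO. Without WT library 1, 2 or 3 or DKO library 10 or 11 the DKO count of 464 became 838, 1640, 1546, 1402 or 1284. The Tet2KO count of 138 became 508, 1154, 1089 or 377 without WT library 1, 2 or 3 or Tet2KO library 5, and the Tet3KO count of 846 became 1933, 1907, 5181 or 3189 without WT library 2 or 3 or Tet3KO library 7 or 9. The planned DKO count was 5, 6, 3, 6, 16 or 7 without library 1, 2, 3, 10, 11 or 12. The planned Tet2KO count was 2, 4, 2, 1 or 1 without library 1, 2, 3, 5 or 6, and the Tet3KO count 6, 5, 5, 40, 4 or 9 without library 1, 2, 3, 7, 8 or 9.

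The test of whether the developmental change itself differed between DKO and WT called few tiles. In the wide set 27 tiles had a higher and 31 a lower change in DKO than in WT, and 11094 of 200813 tiles had an unadjusted p under 0.05. Unchanged groups simulated with each library's spread at similar levels gave 1 higher and 9 lower. With matched libraries as a block 13 tiles were called. The one region with 2 called tiles was chromosome 2, 31353201 to 31353400, which fell from 94.7% ± 1.37 (n = 2) to 63.9% ± 2.06 (n = 3) in WT. It stood at 99.3% ± 1.09 in pro-B and 96.2% ± 1.39 in follicular DKO cells (n = 3 each). The changes differed by 27.8 points (adjusted p = 2.58e-04 and 0.0485 for its tiles). Follicular Tet2KO and Tet3KO cells stood there at 87.7% ± 4.85 and 72.9% ± 3.6 (n = 3 each). Of the planned set 1 tile was called, chromosome 2, 175799701 to 175799800, named after its values were seen. It was listed at 0 in WT pro-B cells and stood at 20.1% ± 5.4 in WT follicular cells. In DKO it stood at 14.7% ± 4.58 in pro-B and 6.30% ± 3.41 in follicular cells (n = 3 each, adjusted p = 0.0334). Of that set 772 tiles (4.82%) had an unadjusted p under 0.05. The wide count of 58 became 306, 665, 656, 640, 374 or 121 without pro-B library 1, 2, 3, 10, 11 or 12 and 112, 136 or 118 without follicular DKO library 22, 23 or 24. The planned count of 1 became 2, 2, 0 or 5 without pro-B library 1, 2, 3 or 10 and 3 without follicular DKO library 23. The named tile itself was not called without pro-B WT library 1, 2 or 3, with the sex covariate, with centring, at 30 points, or with only the compared groups fitted.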

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

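The counts of other splits were planned, and the test of chromosome X by stage and sex was chosen after the values had been seen. Between DKO and WT the developmental change differed at 1 tile of the planned set and at 58 tiles of the wide set, by limma's test of the interaction. Of 100 arrangements of the libraries within their stages, the real one included, 21 called at least 1 planned tile, with 13 as the highest other count. At least 58 wide tiles were called in 89 of 100, with 637 as the highest other count. Relabelling 1 stage alone turns a DKO difference common to both stages into a difference of change, so counts several times the real one can arise from this structure of the samples, and the arrangements do not measure chance here. Unchanged groups simulated with each library's spread at similar levels gave 1 tile higher and 9 lower in the wide set, where 27 and 31 were called. The simulation did not keep the spread of single tiles, so it does not measure chance either.

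The gap in chromosome X methylation between pro-B and follicular libraries was 5.26 points larger in females than in males, over 2180 tiles with a value in 23 libraries. Relabelling the stages within each sex gave a two-sided exact permutation p of 0.0429 for this difference. Such relabelling assumes no stage change in either sex, so it cannot decide whether the rises differ between the sexes. Female libraries stood at 44.1% ± 3.88 in pro-B (n = 5) and 50.7% ± 0.349 in follicular cells (n = 6), a rise of 6.67 points. Male libraries stood at 33.2% ± 0.692 and 34.6% ± 0.292 (n = 6 each), a rise of 1.41 points (two-sided exact permutation p = 0.00216 for each sex, the smallest possible). The pro-B female libraries were spread widely, at 39.2% in DKO library 12 with 273728 tiles, 42.5% in Tet2KO library 6 with 402283, 42.9% in WT library 3 with 425669, 46.6% in Tet2KO library 4 with 532170 and 49.2% in Tet2KO library 5 with 631415. Among these pro-B libraries the level rose at every step in the number of tiles, and the deepest, at 49.2%, was near the follicular 50.7%. Depth and stage therefore cannot be told apart for the female rise. All Tet2KO libraries were female, so sex and genotype overlap in part.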

How the results depend on the processing

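Tests that combined an alternative with the wide tile set, the fit within each stage, the paired fit, the set without the library of fewest tiles, and the alternatives at held-out tiles and named regions were chosen after the data were seen; the others were planned. Counts below are called tiles, and the cause of a changed count was not tested unless stated. With values in at least 2 of 3 libraries per group, which tests more tiles, the planned counts of 1 falling and 8 rising tiles between WT stages became 95 and 268. The 6 higher and 0 lower in follicular DKO became 257 and 2, and the 0 in follicular Tet2KO and Tet3KO 6 and 20. The 1, 0 and 0 in pro-B DKO, Tet2KO and Tet3KO became 464, 138 and 846. The 1, 1 and 3 falling between stages in DKO, Tet2KO and Tet3KO became 59, 40 and 76, and the 1 of the interaction 58. Without the library of fewest tiles, which also tests more tiles, these 13 counts became, in that order, 51, 135, 160, 1, 1, 10, 166, 13, 266, 27, 23, 35 and 12. Centring gave in the planned set 7 falling and 45 rising between WT stages, 35 higher and 1 lower in follicular DKO, and 44 in pro-B DKO. It gave 7, 0 and 19 falling in DKO, Tet2KO and Tet3KO, and 0 for the interaction. Fitting only the compared groups, which leaves 4 residual degrees of freedom for a pair of groups, gave in the planned set 4 rising between WT stages and 0 for follicular DKO higher, pro-B DKO, the falling tiles of the 3 knockouts and the interaction. A difference of 30 points gave 1 rising between WT stages, 3 higher in follicular DKO and 0 for the interaction. Sex and age strata as a block gave 0 falling and 2 rising between WT stages, 0 and 1 falling in Tet2KO and Tet3KO, and 0 for the interaction. Logit values gave 5, 2 and 7 in pro-B DKO, Tet2KO and Tet3KO and 2 for the interaction, the sex covariate gave 1 in pro-B Tet3KO and 0 for the interaction, and the fit within stage gave 11 higher in follicular DKO. In the wide set, fitting only the compared groups gave 31 falling and 62 rising between WT stages, 17 higher and 1 lower in follicular DKO, and 0 and 1 in follicular Tet2KO and Tet3KO. It gave 4, 5 and 29 in pro-B DKO, Tet2KO and Tet3KO, 7, 8 and 0 falling in DKO, Tet2KO and Tet3KO, and 32 for the interaction. The fit within stage gave 449 higher in follicular DKO, 1 and 12 in follicular Tet2KO and Tet3KO, and 35, 13 and 88 in pro-B DKO, Tet2KO and Tet3KO. The block of strata gave 57 falling and 95 rising between WT stages, 26, 17 and 14 falling in DKO, Tet2KO and Tet3KO, and 38 for the interaction. Logit values gave 138 higher and 0 lower in follicular DKO, 0 and 11 in follicular Tet2KO and Tet3KO, 83 in pro-B Tet2KO, 137 falling in Tet3KO and 31 for the interaction. The sex covariate gave 1 lower in follicular DKO, 13 in follicular Tet3KO, 65 and 544 in pro-B Tet2KO and Tet3KO, and 37 and 47 falling in DKO and Tet3KO. Centring gave 155 rising between WT stages, 4 lower in follicular DKO, 1 and 9 in follicular Tet2KO and Tet3KO, and 19 and 767 falling in Tet2KO and Tet3KO. A difference of 30 points gave 0 lower in follicular DKO, 2 in follicular Tet2KO, 91 in pro-B Tet2KO, and 29, 24 and 40 falling in DKO, Tet2KO and Tet3KO. Leaving out 1 library at a time moved the planned counts between 1 and 2 (WT falling), 2 and 12 (WT rising), 5 and 25 (follicular DKO higher), and 0 and 2 (follicular Tet3KO). It moved them between 3 and 16, 0 and 4, and 4 and 40 (pro-B DKO, Tet2KO and Tet3KO), 1 and 4, 0 and 2, and 1 and 15 (falling in DKO, Tet2KO and Tet3KO), and 0 and 5 (interaction). In the wide set these ranges were 69 to 209 falling and 173 to 1138 rising between WT stages, 154 to 425 higher and 3 to 17 lower in follicular DKO, and 10 to 20 and 18 to 64 in follicular Tet2KO and Tet3KO. They were 652 to 1640, 194 to 1154 and 882 to 5181 in pro-B DKO, Tet2KO and Tet3KO, 77 to 163, 34 to 61 and 60 to 720 falling in DKO, Tet2KO and Tet3KO, and 57 to 665 for the interaction. Over the wide set the differences of mean level were 1.30 points (WT follicular minus pro-B), 1.31, 0.427 and 0.912 (follicular DKO, Tet2KO and Tet3KO minus WT). They were 1.43 and 0.993 (pro-B DKO and Tet2KO minus WT), and 1.18, 0.730 and 2.03 (follicular minus pro-B in DKO, Tet2KO and Tet3KO), all in the direction of the planned set, and with X and Y kept the follicular Tet2KO difference was 0.394. The smaller demethylation of DKO at tiles falling in WT, 11.1 points in the wide set, was 32.2 with tiles chosen on all WT libraries, which overstates it by construction, 15.6 with tiles of 30 points, and 2.42 to 12.1 without 1 library. In the planned set, with 1 or 2 tiles, it was -2.41, 0.664 with tiles chosen on all WT libraries, and -9.03 to 3.72 without 1 library, above 0 at 3.72 without pro-B WT library 1 and 1.83 without follicular WT library 13. The held-out difference of 34.0 points at tiles higher in follicular DKO was 43.2 with tiles of 30 points and 17.7 to 27.9 without 1 library. Of the 37 named regions, 36 no longer had 2 called tiles with only the compared groups fitted, 16 on logit values, 8 with the sex covariate, 6 with centring and 5 at 30 points. The fit within stage did so for 8 of 20 regions, and leaving out 1 library in 56 of 228 cases; none changed direction in these alternatives. The planned coverage minimum, count model and weighting by reads were not run because the table holds no reads, and the gene-list alternatives because the lists were not tested. A paired fit was added after the data were seen. No number is given to both a pro-B and a follicular RRBS library, but each pro-B library has a follicular library of the same genotype, sex and age, and these were matched in running order as a replicate block, which leaves 8 residual degrees of freedom. The planned counts became 0 falling and 0 rising between WT stages, 0, 0 and 1 falling in DKO, Tet2KO and Tet3KO, and 0 for the interaction. The wide counts became 11 and 16 between WT stages, 13, 6 and 99 falling in DKO, Tet2KO and Tet3KO, and 13 for the interaction. Blocked fits are approximate at wide tiles with missing values. Whether matched libraries came from the same mouse is unknown, and a call lost under the block is not a weaker effect.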

Other observations

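The tests of conversion, variants linked to Tet2, Tet3 and Mb1, held-out follicular DKO libraries, depth, the library of fewest tiles and the sum of single knockouts with its splits were chosen after the result was seen. The held-out test of pro-B Tet3KO was added after the called tiles were seen, though before its own value was, and the counts of the remaining splits were planned. The regions of this paragraph were singled out after their values were seen. Not every region that lost methylation between the WT stages kept it in the knockouts. At chromosome 5, 32824401 to 32824600, WT pro-B libraries were listed at 100% (n = 2) and follicular cells stood at 73.9% ± 2.27 in WT, 70.9% ± 4.06 in Tet2KO, 71.5% ± 4.16 in Tet3KO and 70.7% ± 9.6 in DKO (n = 3 each). DKO pro-B cells stood there at 96.5% ± 5.37 (n = 3), so the fall was seen in all 4 genotypes, as at chromosome 11, 45538601 to 45538700. Regions that gained methylation between the WT stages were also methylated in the follicular knockouts. Chromosome 13, 24939101 to 24939300, stood at 76.8% ± 2.62 in WT, 70.4% ± 4.73 in Tet2KO, 63.5% ± 3.95 in Tet3KO and 79.3% ± 8.75 in DKO (n = 3 each). Chromosome 10, 40021801 to 40022000, stood at 57.5% ± 1.84, 56.3% ± 5.01, 66.3% ± 3.25 and 55.4% ± 5.63. At held-out tiles rising in WT (335 to 837 tiles of the wide set) the rise was 5.41 points ± 2.12 in WT, 3.76 ± 0.296 in Tet2KO, 4.55 ± 0.233 in Tet3KO and 3.33 ± 0.328 in DKO (n = 3 each). The two-sided exact permutation p against WT was 0.3, 0.8 and 0.1, the last being the smallest possible. Knockout values again share the mean of their pro-B group, so these p-values leave out the spread of those libraries.

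The higher methylation of follicular DKO cells was set against technical explanations, of which incomplete bisulfite conversion would raise unmethylated tiles most, but tiles under 20% were 0.835 points higher in DKO while tiles of 20 to 80% were 5.98 points higher. Variants linked to the targeted genes would gather on chromosomes 3 and 6, which hold Tet2 and Tet3, but called tiles were 0.942 times as frequent there as elsewhere (23 of 18969 tiles against 234 of 181844, two-sided Fisher's exact p = 0.915). On chromosome 7, which holds Mb1, they were 1.62 times as frequent (26 of 13063 tiles against 231 of 187750, two-sided Fisher's exact p = 0.0300) and joined regions 1.38 times (20 against 208, Fisher's exact p = 0.177), so linked variants cannot be told apart from an effect of the knockout for those 26 tiles, since neighbouring tiles are not independent. Noise would leave little difference in held-out libraries, where DKO stood 34.0 points above WT. These values argue against conversion, noise and variants linked to these 3 genes as the whole cause, with 208 of the 257 tiles on other chromosomes, and a loss of Tet-dependent demethylation remains a hypothesis, found and tested on the same libraries.

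Pro-B group means lay below follicular group means of the same genotype at tiles of intermediate methylation, with overlap between libraries in DKO, which may come from their lower number of tiles, and over 11 pro-B libraries the level rose with the number of tiles (r = 0.737, permutation p = 0.00916, adjusted 0.0183; rho = 0.645, permutation p = 0.0371, adjusted 0.0371; r = 0.841 without the 2 libraries farthest from the median). Within genotypes r was 0.791 (exact permutation p = 0.0579 over 432 orders, adjusted 0.116 over 2 stages), and over 12 follicular libraries r was -0.562 (permutation p = 0.0542, adjusted 0.0542), rho -0.636 (permutation p = 0.0305, adjusted 0.0371), r without the 2 farthest -0.405 and r within genotypes -0.162 (exact permutation p = 0.822). At equal tile numbers the pro-B line left 1.04 of the WT gap of 6.44 points, 2.68 of 3.59 in Tet2KO, 3.50 of 5.85 in DKO and 5.76 of 10.1 in Tet3KO (2 pro-B libraries), against a residual SD of 2.45. At these tiles of intermediate methylation, values at exactly 0 or 100% made up 7.55% of pro-B values (n = 11) and 0.370% of follicular values (n = 12, two-sided exact permutation p = 1.48e-06, the smallest possible). Depth and stage cannot be told apart here, because the within-genotype test rests on 11 libraries and misses its threshold, while the part left was small in WT and over 2 residual SDs in Tet3KO, and a biological rise between the stages stays open.

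The tiles called in pro-B Tet3KO were set against noise and against the library of fewest tiles. Held-out Tet3KO and WT libraries differed by 0.695 points at 2631 to 3951 tiles chosen as lower and by 0.589 at 928 to 2586 tiles chosen as higher, where the choosing libraries differed by -45.4 and 44.4. Noise and an effect of Tet3 loss cannot be told apart by this test for the 516 lower and 330 higher called tiles, because most held-out choices rested on a single Tet3KO library and gave longer lists. Only 22 of the 846 called tiles had a value in library 8, so its values did not enter the other 824 calls. It had a value at only 20198 of the 200813 wide tiles, so a low share could be foreseen. The share was 2.60% of called tiles against 10.1% of wide tiles. Most calls thus lay where its missing value left fewer Tet3KO libraries, and the count cannot decide whether that gap contributed to them.

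A hypothesis was that Tet2 and Tet3 stand in for each other, so that the DKO change at tiles falling in WT would exceed the sum of the single knockouts. It exceeded the sum by 3.51 points (SE 1.85), which is under 2 SE, so this test was not decisive. The SE holds no spread of the pro-B knockout libraries and is therefore too small. At held-out tiles chosen as higher in follicular DKO the excess was 2.57 SE (SE 5.07), and with the spread estimated within the stage it was 16.7 points (SE 3.98), but the choice of tiles for a high DKO level favours an excess. Tile by tile, limma called 13 tiles above and 1 below the sum in the wide set, with 7741 at an unadjusted p under 0.05, and 2 above and 0 below in the planned set, with 866. As many tiles were called in 9 of 100 arrangements of the follicular libraries for the wide count of 14 (highest other 21) and in 2 of 100 for the planned count of 2 (highest other 2), but relabelling moves the effects of single genotypes into this contrast, so the arrangements do not measure chance and the hypothesis stays open.

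Other splits of the libraries were counted for each number of called tiles. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only the counts are given. In the planned set the real count and the highest other count were 1 and 0 for tiles falling between WT stages, 8 and 0 for rising tiles, and 6 and 0 for tiles higher in follicular DKO, with 1 of 10 splits as large in each. They were 0 and 0 for tiles lower in follicular DKO and for follicular Tet2KO and Tet3KO (10 of 10 splits). They were 1 and 2 for pro-B DKO (4 of 10), 0 and 2 for pro-B Tet2KO and 0 and 3 for pro-B Tet3KO (10 of 10). For falling tiles between stages they were 1 and 6 in DKO (6 of 10), 1 and 0 in Tet2KO (1 of 10) and 3 and 1 in Tet3KO (1 of 10). In the wide set they were 95 and 11 for tiles falling between WT stages, 268 and 11 for rising tiles, and 257 and 6 for tiles higher in follicular DKO (1 of 10 each). They were 2 and 6 for tiles lower in follicular DKO (9 of 10), 6 and 6 for follicular Tet2KO (2 of 10) and 20 and 4 for follicular Tet3KO (1 of 10). They were 464 and 773 for pro-B DKO (4 of 10), 138 and 320 for pro-B Tet2KO (3 of 10) and 846 and 1823 for pro-B Tet3KO (8 of 10). For falling tiles between stages they were 59 and 86 in DKO (2 of 10), 40 and 4 in Tet2KO (1 of 10) and 76 and 173 in Tet3KO (3 of 10). For counts of 1 direction, the larger of a split and its mirror was taken.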
